A study of Homo sapiens with 6 samples.

How the data were processed

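RNA sequencing was carried out on HCT116 cells, a human colon carcinoma line, in 6 libraries: 3 from untreated cells and 3 from cells given curcumin for 24 h. Curcumin is the yellow polyphenol of turmeric. The labels write the dose as 30 with a unit that reads as micrometres, and it is given here as 30 µM. The untreated samples carry the treatment label none, and a solvent control is not named in the sources used here. Per the labels' protocols, RNA was extracted from lysed cells and made into libraries with a SMARTer mRNA-Seq kit. Nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

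The authors deposited one table of estimated counts per gene, that is, expected read counts, many of which are not whole numbers, with no scaling between libraries. The aligner, the quantification tool and the annotation are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, whereas all 35106 rows of the table carry human Ensembl gene identifiers and 0 carry mouse identifiers. The table was therefore read as human. Of the identifiers, 35003 were found in GENCODE release 29 (GRCh38), which gave gene types, positions, exon numbers and transcript lengths for 19788 protein-coding genes and 14860 pseudogenes. Only 11 rows were long intergenic noncoding RNAs. Symbols that a spreadsheet had turned into dates, 27 in all, were restored through their identifiers. How reads were shared between near-identical genes is not known. Genes with close copies, the genes of the major histocompatibility region on chromosome 6 among them, are therefore uncertain, and so are overlapping and antisense genes, since the use of strand is not stated.

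The estimated counts were rounded to whole numbers, which moved no value by more than 0.5. Library totals ran from 18154387 to 20311774 counts in untreated cells and from 16663567 to 17893061 in curcumin-treated cells. A floor of 3 counts corresponded to 0.148 to 0.165 CPM (counts scaled to the library total) in untreated and 0.168 to 0.180 CPM in treated libraries. This floor covers counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise: chi-square over degrees of freedom between replicates was 11.1 to 71.2.

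Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with edgeR 4.0.16's quasi-likelihood test of curcumin against untreated, over all 6 libraries with no other term (R 4.3.3). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values in the text are TMM-normalised means ± SD (n = 3), fold changes are curcumin over untreated on the log2 scale, and the error of a log2 fold change is its standard error. The TMM factors were 1.30 to 1.34 in untreated and 0.72 to 0.80 in treated libraries.

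Before the data were examined, 27 gene lists with 691 genes were fixed, of which 685 were matched in the table. DERL3, KIF23, KRT20, OAS1, RPL6 and RPL7A were not analysed here. Lists were tested with limma 3.58.1's camera at a preset correlation of 0.01 (adjusted over the 27 lists), and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. The genes named in the text follow a rule fixed at the same time. It takes the 10 protein-coding genes with the largest significant rise and the 10 with the largest fall, given a mean of at least 5 CPM and no overlap between the groups. It adds up to 2 rising and 2 falling members of each list with the smallest adjusted p, and 24 genes chosen from what is known of curcumin and of colon cancer. Other genes named were chosen after their values were seen. Of the lists and genes so selected, 1 list and some genes are not reported here.

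The same results were recomputed with the median-of-ratios (RLE) factors, library size alone, no filter, a mean of at least 50 counts, a minimum fold of 2, the replicate number as a block, each replicate left out in turn, DESeq2 1.42.0 and limma-voom, all chosen in advance. Further settings, chosen after seeing the data, removed each library's trend with transcript length and GC content (loess span 0.3), kept protein-coding genes only, or took the library size without the 100 most abundant genes. Transcript length was that of the longest protein-coding transcript, and 99.94% of the tested protein-coding genes had one.

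The gene test was tested on simulated data for 3 against 3 libraries and 13170 genes. It recovered 41 of 100 genes changed by a fold of 2 and 88 of 100 changed by a fold of 4, and called 4 of 12970 unchanged genes. On 13664 simulated genes, camera called the moved list and 0 of 100 random lists. The simulated genes were drawn independently, so this does not cover lists whose genes move together. In the data the estimated correlation was 0.85 for cytosolic ribosomal proteins. The removal of the length trend took a simulated rank correlation across 13189 genes from −0.81 to −0.029. Python scripts with pandas, SciPy and matplotlib made the remaining tests and the figures.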

Results

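Transcript levels were measured by RNA sequencing in HCT116 colon carcinoma cells, untreated or exposed to 30 µM curcumin for 24 h, with 3 libraries in each group. The study asks how curcumin holds back colon cancer cells, per its title, and its design compares treated with untreated cells, which is the only comparison. Each library held between 16663567 and 20311774 counts.

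Cytosolic heat shock chaperone genes rose as a list after curcumin, a call not kept with an estimated correlation between genes (adjusted p = 0.57). The co-chaperone BAG3 rose from 115 ± 24.0 to 1460 ± 381 CPM (SD, n = 3), and the haem-degrading enzyme HMOX1 rose from 21.4 ± 1.37 to 249 ± 121 CPM. Cytosolic ribosomal protein genes, replication-dependent histone genes and subunits of the respiratory chain rose as groups, calls also not kept with an estimated correlation (adjusted p = 0.57, 0.17 and 0.57). The histone genes rose from low untreated means, 7.86 CPM or less. The transcription factor SOX4 fell from 457 ± 111 to 28.1 ± 6.12 CPM, and Wnt target genes fell as a group, a call lost with an estimated correlation (adjusted p = 0.57) and with the length trend removed (0.078). The proliferation marker MKI67 fell from 232 ± 132 to 71.7 ± 16.4 CPM, a call lost with the length trend removed (edgeR adjusted p = 0.13). Untreated replicate 2 held 382 CPM of MKI67, against 135 and 177 CPM in untreated replicates 1 and 3. Most DNA replication genes did not pass the test.

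Of 13718 genes tested with edgeR's quasi-likelihood test, 3732 were higher and 3964 lower after curcumin, together 56.1% of those tested. With a fold of at least 2 there were 2244 higher and 2386 lower genes. The groups did not overlap for 8778 genes, 64.0% of those tested, where chance gives 10%. The first principal component separated the groups and held 72.5% of the variance. The correlation of log2 CPM across genes was 0.944 to 0.984 within groups and 0.837 to 0.876 between them, a description only, since genes are not independent replicates. The balance of higher and lower genes rested on the scaling, and every rise or fall here is relative to the other transcripts of a library. With library size alone, which moved the median log2 fold change by −0.80, 1320 genes were higher and 7744 lower, and without the 100 most abundant genes in the library size there were 2530 higher and 5583 lower. A call lower under library size alone, for a gene or within a list, therefore carries no weight by itself.

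The make-up of the libraries differed between the groups. The 100 most abundant genes of each library took 21.03 ± 1.91% of counts in untreated and 41.8 ± 1.78% in treated cells (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Cytosolic ribosomal protein genes took 5.84 ± 0.919% and 16.4 ± 0.770%, and mitochondrially encoded genes 4.97 ± 1.75% and 8.39 ± 1.33%, with 2.95% in untreated replicate 2 (exact permutation p = 0.1 for each). Log2 fold change fell with transcript length across 10627 protein-coding genes of at least 5 CPM (Spearman rho −0.50 across genes, which are not independent replicates). Split by length into 5 groups of equal size, the shortest genes (207 to 2019 bases) had a median of 0.78 and the longest (from 5899 bases) a median of −0.78.

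**Figure D1:**
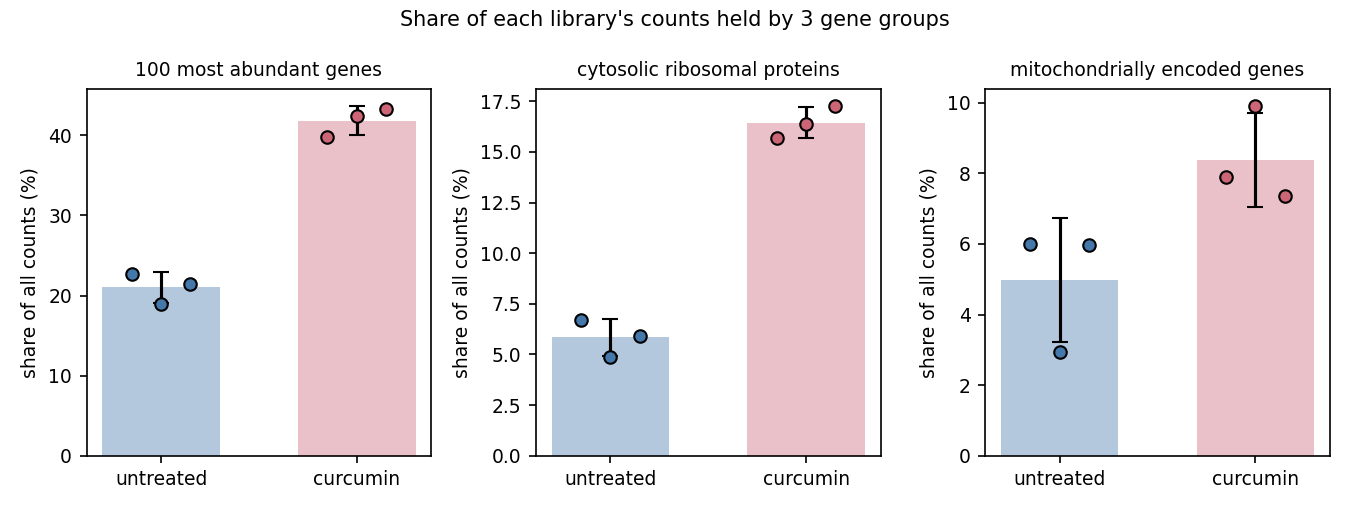
Share of all counts in each library (vertical axes, percent) held by the 100 most abundant genes, the cytosolic ribosomal protein genes and the mitochondrially encoded genes, with points for single libraries, bars for the mean of 3 and whiskers for 1 SD. The share of the 100 most abundant genes was 21.03% in untreated and 41.8% in curcumin-treated cells.

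Heat shock chaperones rose almost throughout. Of the 19 tested cytosolic heat shock chaperones, 18 rose and 0 fell, with a median log2 fold change of 2.51 (18 rose and 0 fell when adjusted over the list alone, and 15 rose and 1 fell with library size alone). The median was 2.51 also with HSPA1B at its bound. Camera called the list higher (adjusted p = 1.2e-07), though not with an estimated correlation (adjusted p = 0.57 with an estimated correlation). BAG3 rose by 3.66 ± 0.24 (adjusted p = 1.1e-05) and DNAJB1, an HSP40 co-chaperone, from 179 ± 38.8 to 1698 ± 391 CPM. The constitutive chaperones HSPA8 and HSP90AB1, chosen after their values were seen, reached 11330 ± 3465 and 17340 ± 6005 CPM from 1097 ± 611 and 2097 ± 691 CPM. HSPA6, a strictly inducible HSP70 gene (ENSG00000173110, chromosome 1, 161524540 to 161526910, a single exon), had 3 counts in all untreated libraries and 12168 in the treated ones, a ratio of 7961 with a 95% counting interval of 2723 to 38610. All 3 untreated counts lay in untreated replicate 3, without which the fitted log2 fold change of 12.74 became 15.45, outside that interval. HSPA1A was listed at 0 in all 6 libraries, and its near-identical neighbour HSPA1B had 0 counts in untreated cells and 54, 106 and 96 in treated cells. Against a floor of 3 counts per library, 0.118 CPM in untreated libraries after TMM scaling, HSPA1B was at least 56.2-fold higher. That bound holds under TMM scaling only and rests on the TMM factors. Reads of this pair may have been shared out or discarded upstream. ZFAND2A, an arsenite- and heat-inducible proteasome-associated gene (chromosome 7, 1152071 to 1160759), rose from 6.19 ± 0.231 to 413 ± 165 CPM.

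Endoplasmic reticulum chaperones also rose as a list (12 rose and 3 fell of 20, both over all genes and adjusted over the list alone, median 0.76, camera adjusted p = 0.017). The call was lost when the correlation was estimated (adjusted p = 0.61 with an estimated correlation), without curcumin replicate 3 (camera adjusted p = 0.057) and when the length trend was removed (camera adjusted p = 0.14). Only 3 of them rose and 4 fell with library size alone (median −0.060). The cyclophilin PPIB and the disulphide isomerase PDIA3 rose by 1.34 ± 0.14 and 1.33 ± 0.16, while EDEM1 and SEL1L, which serve the degradation of misfolded proteins, fell (log2 −0.93 ± 0.21 and −1.23 ± 0.31), neither called once the length trend was removed (adjusted p = 0.14 and 0.16). HSPA5 (BiP) rose from 1043 ± 91.6 to 2104 ± 1320 CPM (adjusted p = 0.030), a rise carried by curcumin replicate 3 and not called without it (log2 fold change 0.37, edgeR adjusted p = 0.10). HSPA5 was also not called without untreated replicate 1, 2 or 3 (adjusted p = 0.094, 0.083 and 0.061), with DESeq2 (0.073), with library size alone (0.63) or without the 100 most abundant genes in the library size (0.11). Of 31 proteasome subunits, 24 rose and 0 fell (25 and 0 adjusted over the list alone; median 0.80, camera adjusted p = 1.9e-05, adjusted p = 0.59 with an estimated correlation). With library size alone, 3 proteasome subunits rose and 2 fell, and with the length trend removed 12 rose and 1 fell and the list was not called (camera adjusted p = 0.073). The core subunit PSMB1 rose by 1.30 ± 0.17 and the ubiquitin receptor PSMD4 by 1.28 ± 0.17, PSMB1 with no call once the length trend was removed (0.29, adjusted p = 0.12).

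The list of ATF4 and integrated stress response targets did not pass (9 rose and 5 fell of 25, the same when adjusted over the list alone; median 0.24, camera adjusted p = 0.27). The balance turned with library size alone, where 4 rose and 12 fell (median −0.56). PPP1R15A, which encodes the eIF2α phosphatase subunit GADD34, rose from 75.4 ± 28.99 to 1862 ± 615 CPM (4.63 ± 0.35, adjusted p = 1.4e-05). DDIT3 (CHOP) rose by 3.34 ± 0.46 and ATF3 by 2.42 ± 0.38, both in all 3 treated libraries. SHMT2, a mitochondrial serine-glycine enzyme, rose by 1.14 ± 0.13 (0.33, adjusted p = 0.052 with library size alone), and the transcription factor CEBPB and the arginine transporter SLC7A1 fell (log2 −2.30 ± 0.24 and −1.67 ± 0.25). GADD45B and GADD45G, growth-arrest and DNA-damage-inducible genes, rose by 5.05 ± 0.29 and 5.28 ± 0.35.

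**Figure D2:**
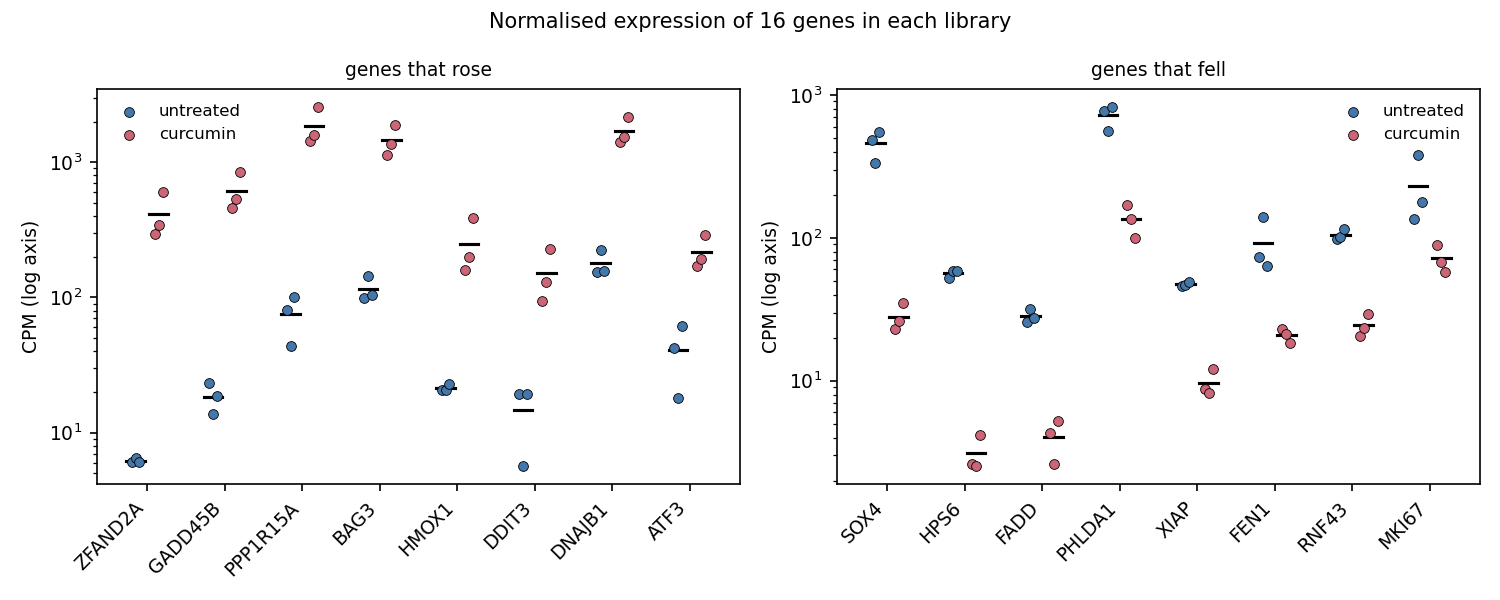
TMM-normalised CPM on a log axis for 8 genes that rose and 8 that fell, with one point per library (3 untreated, 3 curcumin) and black lines at the group means. BAG3 lies at 115 CPM in untreated and 1460 CPM in treated cells, and SOX4 at 457 and 28.1 CPM; the groups do not overlap for any of the 16 genes.

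NRF2 targets and antioxidant enzymes were split. HMOX1 rose by 3.54 ± 0.31 (adjusted p = 1.8e-05) and the pentose phosphate enzyme TKT by 1.56 ± 0.14, whereas GCLC, the catalytic subunit of glutathione synthesis, and the cystine transporter SLC7A11 fell (log2 −1.53 ± 0.18 and −1.60 ± 0.32). NQO1 was 527 ± 57.2 CPM in untreated and 622 ± 132 CPM in treated cells (0.24 ± 0.18, adjusted p = 0.28) and was called lower under library size alone (−0.56, adjusted p = 0.026). In all 14 of 26 rose and 4 fell, the same counts as when adjusted over the list alone (median 0.84, camera adjusted p = 0.030, adjusted p = 0.57 with an estimated correlation). Under library size alone 8 rose and 9 fell (median 0.031). The list was not called without untreated replicate 1 or without any of curcumin replicates 1, 2 and 3 (adjusted p = 0.051, 0.050, 0.096 and 0.078), nor with no filter (0.061) or the length trend removed (0.14), where SLC7A11 was not called either (−0.75, adjusted p = 0.063). Among 24 iron and ferroptosis genes, 10 rose and 6 fell, over all genes and adjusted over the list alone (median 0.27, camera adjusted p = 0.26, called higher by fry at 0.0018). Under library size alone 6 rose and 12 fell (median −0.52). GPX4, the lipid peroxide reductase, rose from 300.1 ± 34.3 to 876 ± 30.7 CPM, and ACSL4 and IREB2 fell (log2 −0.83 ± 0.16 and −1.003 ± 0.20), neither called once the length trend was removed (adjusted p = 0.13 and 0.10). The transferrin receptor TFRC was 161 ± 54.7 and 247 ± 34.0 CPM (0.62 ± 0.22, adjusted p = 0.036) and was not called without untreated replicate 1 or 3 or without curcumin replicate 2 or 3 (adjusted p = 0.15, 0.13, 0.074 and 0.094), nor without the 100 most abundant genes in the library size (0.31) or under library size alone, where it turned to −0.20 (0.45).

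Ribosomal protein genes moved almost as one. Of 72 tested, 71 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 2.34 (camera adjusted p = 3.0e-27, adjusted p = 0.57 with an estimated correlation). RPL36 rose from 91.6 ± 4.77 to 498 ± 40.3 CPM and RPL35 from 210.0 ± 10.7 to 1118 ± 105 CPM. With the length trend removed RPL36 rose by 1.48 and RPL35 by 0.89 in place of 2.44 and 2.41. The list median was 1.58 then and 1.53 under library size alone. Ribosome biogenesis factors did not move together (7 rose and 7 fell of 22, also over the list alone; median −0.27, camera adjusted p = 0.66), and with library size alone 2 rose and 16 fell. The nucleolar proteins FBL and NPM1 rose by 1.71 ± 0.14 and 1.47 ± 0.16, and RRS1 and WDR43 fell (log2 −2.19 ± 0.25 and −1.20 ± 0.16).

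Of 47 nuclear-encoded respiratory chain subunits, 37 rose and 2 fell (39 and 4 adjusted over the list alone), with a median of 1.21 (camera adjusted p = 1.1e-08, adjusted p = 0.57 with an estimated correlation). The counts were 20 and 7 with library size alone (median 0.40). They were 28 and 7 with the length trend removed (median 0.59). COX7C of complex IV rose by 2.27 ± 0.16 and UQCRB of complex III by 2.15 ± 0.14, and the 2 that fell were SDHA (−0.998 ± 0.22) and UQCRFS1 (−0.61 ± 0.17). Of 13 mitochondrially encoded transcripts, 11 rose and 1 fell, the same over the list alone (median 1.58, camera adjusted p = 0.0025, adjusted p = 0.59 with an estimated correlation), a call lost when the length trend was removed (5 rose and 1 fell, camera adjusted p = 0.35). Library size alone left 8 that rose and 2 that fell. MT-ND4L and MT-ND3 rose by 2.48 ± 0.22 and 1.98 ± 0.20. Once the length trend was removed MT-ND4L rose by 0.62 (adjusted p = 0.031) and MT-ND3 had no call (adjusted p = 0.20). MT-ND6, encoded on the opposite strand from the others, fell by 1.55 ± 0.30. Glycolysis and hypoxia-response genes rose as a list (13 rose and 5 fell of 26, 14 and 5 over the list alone; median 0.61, camera adjusted p = 0.040, adjusted p = 0.59 with an estimated correlation). That call was lost without untreated replicate 2 or without curcumin replicate 1 or 3 (adjusted p = 0.089, 0.057 and 0.057), with no filter (0.052) and with the length trend removed (0.086). Scaled by library size alone, 8 rose and 9 fell (median −0.20). GAPDH rose from 3497 ± 461 to 13694 ± 932 CPM and ENO2 from 47.4 ± 6.02 to 179 ± 12.9 CPM, while the glucose transporter SLC2A1 and hexokinase HK2 fell (log2 −1.35 ± 0.19 and −1.18 ± 0.20). VEGFA was 78.7 ± 25.8 and 120 ± 48.0 CPM (adjusted p = 0.11; called higher at 0.037 without curcumin replicate 1 and at 0.043 with the replicate block).

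Wnt/beta-catenin targets were the one list called lower (2 rose and 9 fell of 17, also over the list alone; median −0.65, camera adjusted p = 0.022, adjusted p = 0.57 with an estimated correlation), a call lost when the length trend was removed (camera adjusted p = 0.078). Library size alone gave 0 that rose and 15 that fell. SOX4 fell by 4.03 ± 0.24 (adjusted p = 9.6e-06) and RNF43, a ubiquitin ligase for Wnt receptors, fell by 2.10 ± 0.17. CCND1, which encodes cyclin D1, fell from 602 ± 26.95 to 336 ± 5.67 CPM. CD44 rose from 490 ± 72.7 to 1069 ± 26.3 CPM, without a call under library size alone (0.32, adjusted p = 0.084), and NOTUM, a secreted Wnt inhibitor, rose by 0.45 ± 0.15, with a fold change of −0.35 under library size alone. NOTUM was not called either with no filter, with the length trend removed, without the 100 most abundant genes in the library size, or without untreated replicate 1 or 2 or curcumin replicate 1 or 2 (adjusted p from 0.063 to 0.64). AXIN2 was 34.3 ± 7.70 and 27.4 ± 7.99 CPM (adjusted p = 0.27), and it was called lower without curcumin replicate 3 (adjusted p = 0.030), under library size alone (0.00098) and without the 100 most abundant genes in the library size (0.021). MYC was 285 ± 76.5 and 184 ± 67.0 CPM (−0.63 ± 0.27, adjusted p = 0.067), and was called lower in 7 of 16 alternatives. These were without untreated replicate 2 or curcumin replicate 3 (adjusted p = 0.021 and 0.0048), library size alone (−1.45, adjusted p = 0.00029), the library size without the 100 most abundant genes (0.0059), no filter (0.0041), the replicate block (0.016) and the length trend removed (0.017).

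Neither the DNA replication list nor the mitosis list was called in the main fit. Genes of these lists varied together between replicates (estimated correlations 0.75 and 0.89), so a joint shift is not excluded. Of 36 DNA replication genes, 7 rose and 6 fell (7 and 5 over the list alone; median 0.18, mean −0.030, camera adjusted p = 0.66). Of 29 mitosis genes, 2 rose and 8 fell, the same over the list alone (median −0.40, camera adjusted p = 0.44), and without untreated replicate 3 the mitosis list was called lower (median −0.69, adjusted p = 0.037). Scaled by library size alone, 0 replication genes rose and 19 fell (median −0.62). For mitosis genes, 0 rose and 22 fell (median −1.20). The flap endonuclease FEN1 fell from 92.2 ± 41.8 to 20.9 ± 2.41 CPM and E2F2 fell by 1.53 ± 0.22, while E2F1 and TK1 rose by 1.02 ± 0.18 and 1.23 ± 0.24, neither called under library size alone (adjusted p = 0.34 and 0.13). E2F1 kept its call in 15 of 16 alternatives and TK1 in 14. MKI67 and CENPF fell (log2 −1.69 ± 0.35 and −1.70 ± 0.28), MKI67 with no call once the length trend was removed (adjusted p = 0.13), and BIRC5 (survivin) rose by 0.96 ± 0.26, with no call under library size alone (0.15, adjusted p = 0.62) or without the 100 most abundant genes in it (0.054). UBE2C rose by 0.76 ± 0.25, with no call without untreated replicate 1 or 3 or curcumin replicate 2 (adjusted p = 0.097, 0.078 and 0.087), and with fold changes of −0.044 under library size alone and −0.28 once the length trend was removed. The UBE2C call was kept in 10 of 16 alternatives. CCNB1 was 119 ± 59.5 and 85.0 ± 2.998 CPM (adjusted p = 0.18), and was called lower without untreated replicate 3 (adjusted p = 0.027), under library size alone (−1.29, adjusted p = 0.0021), without the 100 most abundant genes in the library size (0.023) and with no filter (0.033). All 10 tested replication-dependent histone genes rose, also over the list alone (median 2.73, camera adjusted p = 1.8e-06, adjusted p = 0.17 with an estimated correlation). HIST1H1E rose from 0.266 ± 0.132 to 10.5 ± 0.516 CPM and HIST1H2BK from 5.98 ± 0.978 to 31.2 ± 4.10 CPM. Untreated means of the list were low, from 0.0395 CPM for HIST1H3B to 7.86 CPM for HIST1H1C. Which forms of these transcripts the mRNA libraries captured was not tested. With the length trend removed 8 of the 10 rose (median 2) and HIST1H2BK rose by 0.72 in place of 2.38. The median was 1.92 under library size alone.

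**Figure D3:**
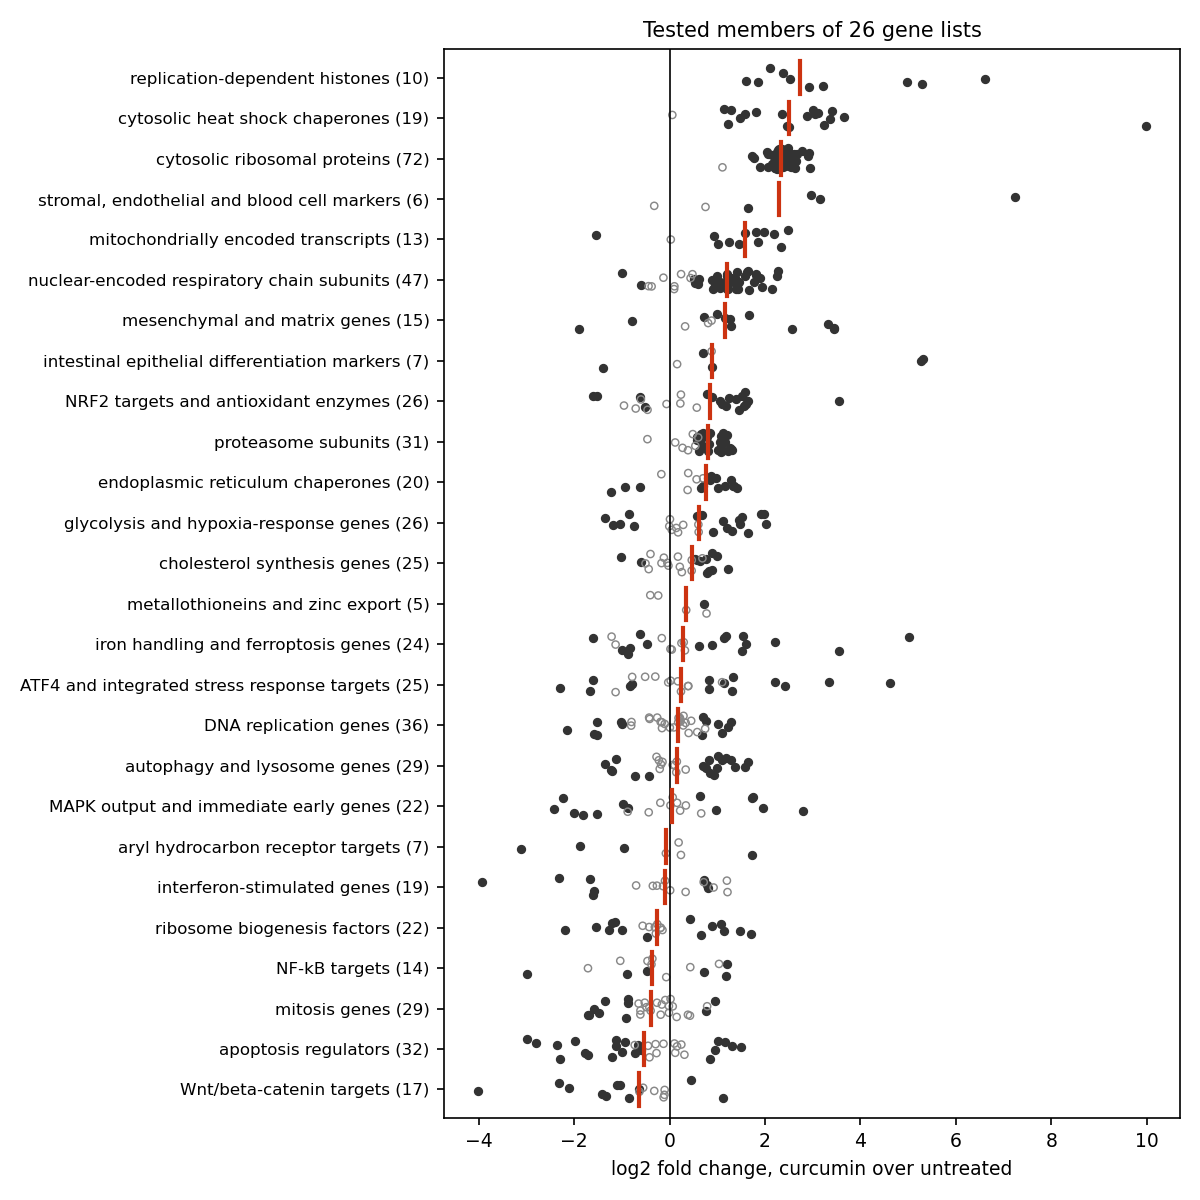
Log2 fold change of curcumin over untreated cells (horizontal axis) for each tested member of 26 gene lists, with the number of members in brackets, filled points for adjusted p under 0.05, open points for the rest and red lines at the medians. The medians run from −0.65 for Wnt/beta-catenin targets to 2.73 for replication-dependent histones, and the point near 10 is HSPA1B, whose fitted value is no bound because its untreated counts are 0.

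Apoptosis and growth-arrest genes went both ways. Of 32 apoptosis regulators, 6 rose and 15 fell, the same over the list alone (median −0.53, camera adjusted p = 0.18; called lower at 0.047 with no filter and at 0.012 by fry), with 2 that rose and 24 that fell under library size alone. CDKN1A (p21) rose from 176 ± 26.6 to 410.2 ± 105 CPM and the pro-apoptotic BAX from 24.4 ± 3.31 to 69.1 ± 6.94 CPM, with CDKN1A not called under library size alone (0.41, adjusted p = 0.066). The antiproliferative gene BTG2 and MDM2, a ubiquitin ligase, fell (log2 −2.29 ± 0.23 and −1.16 ± 0.22), MDM2 with no call once the length trend was removed (adjusted p = 0.33). BAD, which promotes apoptosis, rose by 1.30 ± 0.17. The caspase inhibitor XIAP fell from 47.4 ± 1.41 to 9.68 ± 2.06 CPM and the death-receptor adaptor FADD from 28.4 ± 3.13 to 4.06 ± 1.33 CPM. BCL2 was 4.32 ± 0.883 and 3.95 ± 2.40 CPM (adjusted p = 0.82).

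Of 29 autophagy and lysosome genes, 13 rose and 6 fell, also over the list alone (median 0.15, camera adjusted p = 0.19, called higher by fry at 0.0048). Library size alone turned this to 3 that rose and 16 that fell (median −0.65). The autophagy receptor SQSTM1 (p62) rose from 331 ± 19.8 to 857 ± 24.8 CPM and the protease CTSD from 252 ± 1.60 to 789 ± 78.5 CPM, while the initiation factors ULK1 and ATG14 fell (log2 −1.35 ± 0.17 and −1.22 ± 0.18). Cholesterol synthesis genes gave 10 that rose and 2 that fell of 25 (9 and 2 over the list alone; median 0.46, camera adjusted p = 0.17), but with library size alone 0 rose and 12 fell. DHCR7 rose by 0.89 ± 0.13, with no call under library size alone (adjusted p = 0.64), and SQLE and STARD4 fell (log2 −1.02 ± 0.24 and −0.59 ± 0.15), STARD4 with no call once the length trend was removed (adjusted p = 0.44). HMGCS1 was 41.8 ± 15.3 and 41.1 ± 11.3 CPM (adjusted p = 0.95) and was called lower under library size alone (−0.85, adjusted p = 0.014).

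Signalling outputs were mixed. Of 22 MAPK output and immediate early genes, 6 rose and 7 fell (6 and 8 over the list alone; median 0.042, mean −0.094, with camera pointing down at adjusted p = 0.80). The AP-1 genes FOS and FOSB rose by 1.96 ± 0.26 and 2.80 ± 0.29, and PHLDA1 and SPRED2 fell (log2 −2.42 ± 0.22 and −1.80 ± 0.22). Of 14 NF-kB targets, 3 rose and 3 fell (2 and 3 over the list alone; median −0.37, camera adjusted p = 0.79), with RELB and NFKB2 up by 1.20 ± 0.29 and 0.73 ± 0.21 and BIRC3 and NFKB1 down (log2 −2.99 ± 0.50 and −0.89 ± 0.18). NFKB2 had a fold change of −0.071 and RELB no call (adjusted p = 0.23) under library size alone. NFKB2 kept its call in 14 of 16 alternatives and RELB in 15. Of 19 interferon-stimulated genes, 3 rose and 5 fell, also over the list alone (median −0.097, camera adjusted p = 0.80). The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) fell (log2 −1.61 ± 0.28 and −1.68 ± 0.37), and ISG15 rose by 0.79 ± 0.17, with fold changes of −0.29 once the length trend was removed and −0.0067 under library size alone, and no call without the 100 most abundant genes in the library size (adjusted p = 0.064). Of 7 aryl hydrocarbon receptor targets, 1 rose and 3 fell, also over the list alone (median −0.079, camera adjusted p = 0.55, called lower by fry at 0.038), and CYP1A1 fell from 2.26 ± 0.658 to 0.252 ± 0.310 CPM (log2 −3.11, adjusted p = 0.0091; −4.74 without curcumin replicate 1). Of 5 metallothionein and zinc export genes, 1 rose and 0 fell, also over the list alone (median 0.35, camera adjusted p = 0.66), and MT2A was 269 ± 34.2 and 343 ± 67.8 CPM (adjusted p = 0.12; called higher at 0.020 without curcumin replicate 3, and lower once the length trend was removed, −0.75, adjusted p = 0.0035). Falls outnumbered rises in all 5 of these lists with library size alone: 4 rose and 13 fell for MAPK output, 0 and 8 for NF-kB, 0 and 10 for interferon, 0 and 6 for the aryl hydrocarbon receptor, and 0 and 2 for metallothioneins. Under that scaling 7744 of all 13718 genes were called lower, so these falls are no support.

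Mesenchymal and matrix genes rose as a list (10 rose and 2 fell of 15, also over the list alone; median 1.16, camera adjusted p = 0.0086, adjusted p = 0.57 with an estimated correlation), and with library size alone 5 rose and 3 fell. The matrix glycoprotein THBS1 rose from 21.7 ± 3.45 to 237 ± 107 CPM and the transcription factor SNAI1 from 12.5 ± 0.232 to 136 ± 33.3 CPM, whereas TWIST1 and the integrin ITGA5 fell (log2 −1.90 ± 0.48 and −0.79 ± 0.23), ITGA5 with no call without curcumin replicate 2 or with the length trend removed (adjusted p = 0.056 and 0.061). Of the 28 intestinal differentiation markers only 7 could be tested, of which 4 rose and 1 fell, also over the list alone (median 0.88, camera adjusted p = 0.14; called higher at 0.044 with no filter and at 0.012 by fry), and with library size alone 2 rose and 2 fell. LGALS4 had 4 counts in all untreated libraries and rose to 2.35 ± 0.397 CPM, EPCAM rose by 0.89 ± 0.15 with no call under library size alone (adjusted p = 0.63), and CDX2, an intestinal transcription factor, fell by 1.40 ± 0.23.

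Markers of stromal, endothelial and blood cells were called higher with 6 testable members, 4 of which rose and 0 fell, also over the list alone (median 2.30, camera adjusted p = 0.040, adjusted p = 0.57 with an estimated correlation). The call was lost without untreated replicate 2 or curcumin replicate 3 (adjusted p = 0.068 and 0.11), with no filter (0.25) and with the length trend removed (0.073). PECAM1 rose from 0.0936 ± 0.0828 to 14.9 ± 9.33 CPM (log2 7.24, and 6.64 and 6.65 without untreated replicate 1 and without curcumin replicate 3) and CD68, a lysosomal protein of macrophages, from 2.76 ± 0.581 to 21.7 ± 8.09 CPM. Of further stromal and blood transcripts, LYZ (lysozyme) rose from 0.160 to 1.47 CPM (adjusted p = 0.0033) and the globin gene HBA1 from 0.537 to 1.69 CPM (adjusted p = 0.042). COL1A2, COL3A1, DCN, LUM, PTPRC and HBB stayed at or below 0.440 CPM in treated cells, and COL1A1 was 28.6 ± 2.65 and 22.9 ± 12.7 CPM.

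Several of the largest rises were in genes almost silent in untreated cells. PNLDC1 (ENSG00000146453, chromosome 6, 159800249 to 159820704, plus strand) rose from 0.117 ± 0.0655 to 38.1 ± 19.2 CPM (8.26 ± 0.52, adjusted p = 1.1e-05). The gene starts 1813 bases beyond the end of MRPL18 on the same strand, which rose from 41.4 ± 12.5 to 278 ± 98.2 CPM. COL2A1 had 0, 0 and 5 counts in untreated and 122, 156 and 308 in treated libraries. It was 128.3-fold higher against a TMM-scaled floor of 3 counts per library. This is no lower bound, since untreated replicate 3 lay above the floor. Its fitted log2 fold change of 7.72 ± 0.76 became 11.08 without untreated replicate 3, which holds all its untreated counts. CD14 rose by 5.74 ± 0.48 and SERPINC1 by 5.20 ± 0.52, to treated means of 19.2 and 11.8 CPM. Other large rises did not all lie so close to a facing 3′ end of a gene of at least 10 CPM. That end was 5039 bases away for CD14 (same strand) and 4087 for COL2A1 (opposite strand). It was 13836 bases away for SERPINC1, 64009 for PECAM1 and 149200 for HSPA6.

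The largest falls were in HPS6, a subunit of a lysosome-related organelle complex (ENSG00000166189, chromosome 10, 102065390 to 102068038, a single exon), from 56.7 ± 3.64 to 3.10 ± 0.905 CPM (−4.19 ± 0.23, adjusted p = 9.6e-06), and in SOX4 (ENSG00000124766, chromosome 6, 21592768 to 21598619, a single exon). ZNF469, TMEM177, WNT6, TIGD5 and FAM217B fell (log2 −3.98 ± 0.36, −3.84 ± 0.33, −3.80 ± 0.42, −3.63 ± 0.21 and −3.55 ± 0.27), and DEPP1 fell by 3.53 ± 0.73 (log2 −5.22 without curcumin replicate 3). PPP1R3B, a glycogen-targeting phosphatase subunit, had 702, 391 and 641 counts in untreated cells and 0, 0 and 58 in treated cells (adjusted p = 0.0058; 0.16 with DESeq2), so that without curcumin replicate 3 it is listed at 0 in treated cells. TRIM27, which lies in the histocompatibility region and is uncertain for that reason, fell by 3.85 ± 0.64 (log2 −4.62 without curcumin replicate 3).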

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

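The length and GC correction, the restriction to protein-coding genes and the library size without the 100 most abundant genes were chosen after the data were examined, and the other settings before. The counts of higher and lower genes stayed within 1.5 times of 3732 and 3964 with RLE factors, no filter, at least 50 counts, the replicate block (3683 and 4011), DESeq2, limma-voom, protein-coding genes only (3633 and 3861), the trend removed (3546 and 3089), the library size without the 100 most abundant genes (2530 and 5583), and each replicate left out. They were 2244 and 2386 with a fold of at least 2, which is a stricter rule by construction, and 1320 and 7744 with library size alone, where 50 genes called higher with TMM were called lower, because that scaling moved the median by −0.80. The list counts, 11 higher and 1 lower, became 0 and 0 with an estimated correlation, the smallest adjusted p being 0.17. They became 5 and 0 once the trend was removed, 14 and 4 with fry and 2 lower with no filter, and ran from 7 to 11 higher and from 1 to 2 lower with a replicate left out, 7 without curcumin replicate 3 and 2 without untreated replicate 3; the cause was not tested. With library size alone the fold change turned negative for UBE2C (−0.044), NOTUM (−0.35), NFKB2 (−0.071), ISG15 (−0.0067), MT1E (−0.063), NQO1 (−0.56, adjusted p = 0.026), TFRC (−0.20), MT2A (−0.45) and VEGFA (−0.21). With the trend removed it was −0.28 for UBE2C, −0.29 for ISG15, −0.031 for IFI35, −0.53 for MT1E, −0.75 for MT2A (adjusted p = 0.0035), 0.56 for BCL2 and 0.21 for HMGCS1. Without the 100 most abundant genes in the library size it was −0.12 for NQO1 and −0.0084 for MT2A. HMGCS1 was −0.85 with library size alone (adjusted p = 0.014), 0.018 with RLE factors, 0.021 with at least 50 counts, 0.00056 with the block, 0.018 with DESeq2 and 0.0063 with limma-voom. Camera's direction turned, with no call, for the MAPK list (median −0.77) and the NF-kB list (−1.19) with library size alone, for the NF-kB list with at least 50 counts (−0.32) and for metallothioneins with the trend removed (−0.53). Leaving out a replicate gave medians of 0.013 to 0.45 for the ATF4 list, −0.69 to 0.15 for mitosis, −0.077 to 0.41 for DNA replication, −0.26 to 0.26 for MAPK output, −0.51 to 0.38 for NF-kB and −0.13 to 0.10 for interferon genes, and fold changes of −0.73 to 0.17 for BCL2 and −0.27 to 0.29 for HMGCS1. Deviations of libraries with the same replicate number correlated at 0.0396, 0.0229 and 0.111, not all above 0.1, so the numbers were not read as pairing the samples. The block changed no list call and, among named genes, added MYC (adjusted p = 0.016) and VEGFA (0.043) and lost IFI35 (0.052). At this depth the simulated recovery was 41 of 100 genes at a fold of 2, so genes that missed the threshold may still differ by that much.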

Other observations

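Gene families chosen by symbol after the data were examined moved in several directions, each given with camera adjusted over the 10 families. Because the choice followed the data, the p-values of all these families are descriptive only. Of 410 zinc finger genes 46 rose and 167 fell (median −0.67, adjusted p = 9.4e-05, adjusted p = 0.47 with an estimated correlation). The SOX, FOX and HOX transcription factors gave 4 that rose and 30 that fell of 67 (−0.52, adjusted p = 0.0039, adjusted p = 0.41 with an estimated correlation), among them FOXC1, from 219.5 ± 46.9 to 31.1 ± 6.13 CPM, and SOX12, from 96.3 ± 15.4 to 23.2 ± 1.43 CPM. Of 15 KLF factors 9 fell and 1 rose (−1.65, adjusted p = 0.026, adjusted p = 0.47 with an estimated correlation). With library size alone 20, 3 and 0 genes of these families rose and 290, 47 and 11 fell. That scaling called 7744 of all 13718 genes lower, so the falls under it are no support. With the length trend removed 48, 5 and 1 rose and 123, 33 and 9 fell. Exon number was not taken into account for these families. Genes with 1 or 2 exons had medians of −1.13 and −0.61, so exon number stays open as a source of these falls.

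Protein-making and folding families were mixed. Of 9 subunits of TRiC, the chaperonin that folds actin and tubulin, 8 rose and 0 fell (median 1.19, adjusted p = 8.8e-04, adjusted p = 0.41 with an estimated correlation), with TCP1 at 264 ± 85.3 and 1717 ± 533 CPM, and 3 rose and 0 fell with library size alone. Of 52 translation initiation factors 31 rose and 7 fell (0.64, adjusted p = 4.4e-04, adjusted p = 0.41 with an estimated correlation), but with library size alone 17 rose and 18 fell. Of 20 cytosolic aminoacyl-tRNA synthetases 11 rose and 1 fell (adjusted p = 0.019, adjusted p = 0.41 with an estimated correlation), though 2 rose and 9 fell with library size alone, and their 16 mitochondrial counterparts gave 3 that rose and 9 that fell (median −0.88, adjusted p = 0.089, adjusted p = 0.49 with an estimated correlation), 0 and 12 with library size alone, and were called lower once the length trend was removed (−0.60, adjusted p = 0.024). The other 3 families lost their call once the length trend was removed. Mitochondrial ribosomal proteins gave 31 that rose and 10 that fell of 77 (median 0.19, adjusted p = 0.019, adjusted p = 0.60 with an estimated correlation; −0.051, adjusted p = 0.15 without the trend), and small nuclear ribonucleoproteins 12 and 3 of 24 (0.69, adjusted p = 0.026, adjusted p = 0.52 with an estimated correlation; 0.12, adjusted p = 0.75 without the trend). Of 44 ubiquitin-specific proteases 6 rose and 21 fell (−0.35, adjusted p = 0.026, adjusted p = 0.41 with an estimated correlation; 0.070, adjusted p = 0.70 without the trend). With library size alone these 3 families gave 8 that rose and 39 that fell, 4 and 9, and 1 and 36. The polyubiquitin gene UBB rose from 869 ± 94.3 to 4880 ± 1293 CPM. NR4A1 and NR4A3, inducible nuclear receptors, rose to 478 ± 67.9 and 34.7 ± 5.81 CPM from 45.3 ± 12.7 and 1.80 ± 0.249 CPM.

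Of the tests that follow, those on cell types, genomic DNA, transcript length, the scaling and other splits of the libraries, and the counts by strand, were chosen after the result was seen, and the comparison of neighbouring 3′ and 5′ ends before. Among 6533 protein-coding genes under 1 CPM in untreated cells and not overlapping an expressed gene, 297 rose, 217 of them also with library size alone. Some markers of other cell types rose, within this set or above its limit, CD14 from 0.350 to 19.2 CPM, CD68 from 2.76 to 21.7 CPM, and LYZ and HBA1 to 1.47 and 1.69 CPM. The tables argue against stromal and white blood cells as the source, since the median of 8 of their abundant transcripts in treated libraries was 0.21 CPM against 14.9 CPM for PECAM1, with PTPRC, common to white blood cells, at 0.289 CPM. The endothelial gene CDH5 had 3, 2 and 3 counts in untreated and 0, 1 and 0 in treated libraries, and VWF was 1.58 ± 0.395 and 2.68 ± 0.904 CPM. Cell types whose abundant transcripts were not examined stay open. The odds of rising were 6.21 times higher (exact 95% interval 4.70 to 8.17) with a neighbour's 3′ end within 10 kb than with no expressed neighbour there. Genes left out by the filter on low counts were never tested and count here as not rising. This ratio, and the shares and odds ratio below, therefore mix passing the filter with rising. The 6.21 thus does not settle whether genomic DNA was the whole cause. Genomic DNA as part of the cause stays open, as near-silent olfactory receptor genes summed to 9.19 to 18.8 CPM in treated libraries and 2.73 to 5.04 CPM in untreated ones, or 7.38 to 13.4 and 3.54 to 6.68 CPM by library total. Part of the rise may come from transcription that ran past the 3′ ends of expressed neighbours: 104 of 726 genes facing only such an end rose against 38 of 404 facing only a 5′ end, an odds ratio of 1.61 (exact 95% interval 1.07 to 2.45, Fisher's exact p = 0.019). In all, 120 of the 297 had a neighbour's 3′ end within 10 kb. Such transcription does not cover the 38 facing only a 5′ end, nor the 139 with no expressed neighbour within 10 kb. Those 139 were 2.62% of 5300 genes without such a neighbour, and genes facing only a 5′ end also rose more often than that (9.41%). By strand, 25.6% of 289 genes downstream of a neighbour on the same strand rose, against 6.87% of 437 facing a 3′ end on the opposite strand and 8.71% and 10.4% of those facing a 5′ end on the same or opposite strand. A transcription start of their own was not tested and stays open for these genes, which include PNLDC1 beyond MRPL18.

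The joint rise of ribosomal protein, respiratory chain and proteasome genes was set against transcript length with 10000 random lists matched on length. None of the random lists (0%) reached the ribosomal protein median of 2.34 (highest 1.20; 1.53 when matched on mean expression too), which argues against length as its whole cause. The respiratory chain median was reached by 0.1%, or 0.25% with mean expression. Random genes were drawn independently, whereas genes of these lists move together (estimated correlations 0.85 and 0.64). Random medians thus spread too little, and for the respiratory chain the shares do not decide. The ribosomal protein median stayed at 1.53 under library size alone, above its members' SD of 0.258, though members are not replicates. Both scalings compare shares of a library. They cannot tell a rise per cell from a loss of other transcripts. For proteasome subunits 10.3% of random lists had a median as high, and 67.9% when matched on mean expression too, so their rise may reflect the length trend. For the Wnt/beta-catenin targets 7.15% had a median as low when matched on length, and 1.23% with mean expression too, so length stays open there. The length trend itself was not confined to the group difference, since single libraries differed from the other 2 of their group with rho from −0.35 to 0.35 across genes. Whether it came from the RNA, the library preparation or the cells was not tested, and a response to curcumin remains open.

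Single-exon genes fell: of 184 with at least 5 CPM, 118 fell and 33 rose (median −1.13), against −0.61 for genes with 2 exons, −0.18 with 3 and −0.054 with 4 or more. The tables argue against length as the whole cause, as 0% of 10000 length-matched lists of other genes had a median as low (lowest −0.16). They argue against genomic DNA in the untreated libraries too, as the summed CPM of 369 olfactory receptor genes under 1 CPM, a limit set after OR51B5 was seen to hold most of the first sum, was 3.84 ± 1.16 in untreated and 14.4 ± 4.83 in treated libraries, a ratio of 0.27 that rests in part on the TMM factors. The replication-dependent histones, also mostly single-exon, rose. A curcumin effect on transcripts that lack introns is a candidate explanation that no test here addressed, and how the counting treated such genes is not known.

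Splitting the 6 libraries 3 against 3 in all 10 ways gave 7696 called genes for the real split and at most 0 for any other, so that 1 split gave as many. For the gene lists the real split called 12 and the highest other 15, and 6 of the 10 splits called at least 12. With 10 splits no share under 0.05 can be reached, so the splits are too few to set the real gene count apart by this test. For the lists, other groupings of the same libraries gave as many calls or more. Every other split holds libraries of both groups on each side. Part of the curcumin difference thus stays in its contrast, and the rest widens its spread. Such splits are no null groupings, so neither the gene count nor the list count sets the real grouping apart by this test.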
